A study of Mus musculus with 11 samples.

How the data were processed

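Per the labels' protocols, stem cells pooled from 3 mice per sample were sorted, RNA of 1000 cells was reverse transcribed with poly-dT priming and template switching, amplified over 17 PCR cycles, and 1.5 ng of cDNA was tagmented, indexed over 12 cycles and sequenced on a NextSeq 500. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned with STAR and counted per gene with HTSeq 0.6.1p1, with GRCm38 and mm10 named as genome builds. The deposited values were the counts per gene produced by the authors in this way, and they were used here without rescaling. The strand setting and the annotation release of that counting are not given in the sources used here, and reads were not analysed here. Of 49585 entries in the table, 49326 carried an identifier with a symbol in GENCODE M21, 259 did not, 66 symbols stood on several identifiers and 24487 entries were 0 in all libraries.

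The 11 libraries were assigned to 4 groups by treatment and CD41 from their labels, with replicate numbers in order of deposit. No batch or pairing was given, so none was modelled. Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 13448 genes with 99.7% of counts. Counts were normalised by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 (robust) in R 4.3.3, with 1 coefficient per group. The 7 comparisons were CD41+ against CD41- cells in control mice, in depleted mice and on average, depleted against control mice in CD41- cells, in CD41+ cells and on average, and the difference of the depletion responses. Each was adjusted by Benjamini-Hochberg at 0.05, and the SE is the absolute log2 fold change over the square root of F. Comparisons and settings were fixed before the data were examined.

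Lists of genes were written from general knowledge, 31 lists with 640 genes, of which 1 was not in the table. The sort gate genes were read 1 by 1, and 30 lists with at least 5 measured members were tested by camera of limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and by fry. Named genes were the sort genes, the 8 largest increases and decreases (6 for single groups) among called genes with a mean of at least 5 CPM and no overlap of libraries, and up to 4 members with the smallest p of each list. For the difference of responses, the genes with the smallest p were named. A fold against a group without counts is given as a lower bound from a floor of 3 counts over the group.

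Alternatives were RLE factors, library size alone, no filter, the fit without robust, DESeq2 1.42.0, limma voom with sample quality weights, fits on the groups compared only, a block of consecutive title numbers, and leaving out each library. A neutrophil score as covariate was added after the results were seen. The procedure was tested on simulated data, in 3 simulations per comparison with 200 changed genes spread over folds of 1.5, 2 and 4. Of the genes at a fold of 2 it recovered 8.96%, 17.4%, 15.9% and 12.9% in the 4 single comparisons, in the order control, depleted, CD41- and CD41+. It recovered 40.3% and 42.3% in the averages and 1.99% in the difference of responses. In the same order, false calls made up 3.65%, 7.56%, 4.6% and 5.71% of calls, 6.72% and 6.15% in the averages and 12% in the difference of responses. Simulated genes varied independently, with 1 dispersion per gene for all libraries. These rates thus do not cover correlated genes, RNA of other cells or libraries of unequal quality. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.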

Results

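Haematopoietic stem cells were sorted from the bone marrow of C57BL/6 mice as lineage-negative, c-Kit+ Sca-1+ cells that lacked CD48 and carried CD150, and were divided by surface CD41, the integrin alpha chain best known from megakaryocytes and platelets. They came from control mice given rabbit serum and from mice 24 h after depletion of their platelets, and each library held cells pooled from 3 mice. The 11 libraries formed 4 groups, with 3 of control CD41- cells, 2 of control CD41+ cells, 3 of depleted CD41- cells and 3 of depleted CD41+ cells. Deposited gene counts added up to between 0.974 M (depleted CD41+ replicate 1) and 9.95 M (depleted CD41- replicate 1) per library, with a median of 3.88 M. A floor of 3 counts corresponded to between 0.302 and 3.08 CPM, counts scaled to a common library total, depending on the library. Intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Values below are TMM-normalised CPM as mean ± SD over the libraries of a group (n = 3, 2, 3 and 3 in the order above) and log2 fold changes ± SE, with edgeR quasi-likelihood tests adjusted by Benjamini-Hochberg over 13448 genes. The strand setting used in counting is not given in the sources used here, so values of antisense, overlapping and paralogous genes are less certain than the rest.

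How stem cells with surface CD41 differ from those without it was addressed by the CD41 difference averaged over control and depleted mice. Transcripts of the megakaryocyte lineage were more abundant in CD41+ cells. Of 31 measured megakaryocyte genes, 14 were higher, 0 were lower and 17 did not pass (18 higher and 2 lower when adjusted over the list alone), with a median log2 fold change of 0.82. Gp1bb (ENSMUSG00000050761, GRCm38 chromosome 16, 18620317 to 18622403, minus strand), a subunit of the platelet receptor for von Willebrand factor, was 10.9-fold higher (log2 3.45 ± 0.38, adjusted p = 0.000372). Its level was 36.9 ± 10.9 CPM in control and 19.2 ± 8.61 CPM in depleted CD41+ cells, against 3.26 ± 1.55 and 1.82 ± 1.02 CPM in CD41- cells. Gp5, which joins the same receptor complex, was higher by 2.35 ± 0.23 (adjusted p = 0.000193), and Treml1, a receptor stored in platelet granules, by 2.38 ± 0.36 (adjusted p = 0.00281). Gata1 (chromosome X, 7959260 to 7978071, minus strand), a transcription factor of megakaryocytes and erythroid cells, was 4.26-fold higher (adjusted p = 0.00236). Among 18 transcripts abundant in platelets, 7 were higher and 0 lower (8 and 0 when adjusted over the list alone), including Clu at 1.81 ± 0.20 (adjusted p = 0.000372). Camera, a test of whether the genes of a list rank higher or lower than all other genes, called both lists (adjusted p = 2.05e-17 and 1.3e-12). These were the only 2 of 17 lists called in this comparison that also passed with a correlation estimated from the data (adjusted p = 0.0177 with an estimated correlation for the megakaryocyte list, and 0.0336 for the platelet list). Many genes, such as Gp1bb, Gp5 and Treml1, stand on both lists, so the 2 results are not independent.

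The genes behind the sort markers were read 1 by 1. Itga2b (ENSMUSG00000034664, chromosome 11, 102453297 to 102470122, minus strand), which encodes CD41, was 5.31-fold higher in CD41+ cells (log2 2.41 ± 0.18, adjusted p = 2.01e-05), with 389 ± 49.9 CPM in control CD41+ and 69.0 ± 26.8 CPM in control CD41- cells. Ly6a, the gene of Sca-1, was lower by -1.47 ± 0.26 (adjusted p = 0.00794, and 0.0519 without control CD41+ replicate 2). Slamf1, the gene of CD150, was higher by 0.75 ± 0.19 (adjusted p = 0.0362, and 0.112 without control CD41+ replicate 1). Kit at -0.53 (adjusted p = 0.487) and Cd48 at 0.57 (adjusted p = 0.352) did not pass.

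Some genes tied to stem cell identity and to lymphoid potential were lower in CD41+ cells. Of 22 long-term stem cell genes, 4 were lower and 1 higher (9 lower and 3 higher when adjusted over the list alone), with a median log2 fold change of -0.46. Hlf (chromosome 11, 90336536 to 90390895, minus strand), a transcription factor that marks stem cells, was 2.67-fold lower (log2 -1.42 ± 0.17, adjusted p = 0.000928). Procr (ENSMUSG00000027611, chromosome 2, 155751117 to 155755471, plus strand), the endothelial protein C receptor used to purify stem cells, was 2.68-fold lower with the same adjusted p. The list was called by camera (adjusted p = 0.00103), but not with its own correlation (adjusted p = 0.279 with an estimated correlation). Its median was -0.26 without control CD41+ replicate 2, -0.28 without depleted CD41- replicate 2 and -0.25 with a neutrophil score as covariate. Of 12 lymphoid genes, 3 were lower and 0 higher, both over all genes and when adjusted over the list alone. Flt3 (chromosome 5, 147330741 to 147400489, minus strand), a receptor tyrosine kinase of lymphoid-primed progenitors, was 3.92-fold lower (log2 -1.97 ± 0.25, adjusted p = 0.00145) and Cd27 was lower by -0.92 ± 0.13 (adjusted p = 0.00232). The lymphoid list as a whole was not called (adjusted p = 0.111), and its median of 0.14 and mean of -0.04 differed in sign. With the neutrophil score as covariate, camera called it lower in control mice (median -0.67, adjusted p = 0.0118) and in depleted mice (-0.30, adjusted p = 0.000596). Among the largest decreases outside the lists were Zfp608 (log2 -2.40 ± 0.29, adjusted p = 0.000928), Epb41l3 (-2.26 ± 0.32, adjusted p = 0.00227), Pcp4l1 (-2.07 ± 0.21, adjusted p = 0.000247) and Palld (-1.99 ± 0.28, adjusted p = 0.00227). Among 18 erythroid genes, 2 were higher and 0 lower (4 and 0 when adjusted over the list alone), namely the water channel Aqp1 (1.67 ± 0.24, adjusted p = 0.00236) and the erythropoietin receptor Epor (1.28 ± 0.21, adjusted p = 0.00521). That list had a camera adjusted p of 1.92e-06 and an adjusted p = 0.238 with an estimated correlation, and its median of 0.88 was 1.34 without depleted CD41- replicate 1 and 0.46 with the neutrophil score as covariate.

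Cell-cycle transcripts were higher in CD41+ cells on average, mostly through control mice. Of 34 genes of DNA replication, 17 were higher and 0 lower (24 and 0 when adjusted over the list alone), with a median log2 fold change of 0.50. Of 32 mitosis genes, 15 were higher and 0 lower (24 and 0 when adjusted over the list alone), with a median of 0.65. Rrm1, a subunit of ribonucleotide reductase, was higher by 0.78 ± 0.11 (adjusted p = 0.00195), Ccne2, the S-phase cyclin E2, by 1.14 ± 0.15 (adjusted p = 0.00156) and Ccnb1, the mitotic cyclin B1, by 1.03 ± 0.15 (adjusted p = 0.00227). Both lists were called by camera (adjusted p = 7.17e-17 and 2.05e-17), and both had an adjusted p = 0.0889 with an estimated correlation. The mitosis median was 1.18 in control mice and 0.12 in depleted mice, where camera did not call the list (adjusted p = 0.205). For replication the medians were 0.79 and 0.13, and camera called both. All 30 proteasome genes had positive fold changes, with 3 higher and 0 lower (14 and 0 when adjusted over the list alone, adjusted p = 2.11e-08, and adjusted p = 0.216 with an estimated correlation), and the deubiquitinase subunit gene Psmd14 stood at 0.72 ± 0.14 (adjusted p = 0.0122).

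Mitochondrially encoded and some interferon-response transcripts were less abundant in CD41+ cells. Of 7 measured mitochondrial genes, 5 were lower and 0 higher (6 and 0 when adjusted over the list alone), with mt-Nd5 at -0.95 ± 0.12 (adjusted p = 0.000928) and mt-Co1 at -0.99 ± 0.13 (adjusted p = 0.00126). The camera adjusted p was 1.58e-09, with an adjusted p = 0.0978 with an estimated correlation. Of 34 interferon-response genes, 6 were lower and 0 higher (9 and 0 when adjusted over the list alone), among them Gbp7 at -1.11 (adjusted p = 0.0118, and 0.0631 without control CD41+ replicate 1). That list's median was -0.52 (adjusted p = 2.19e-06, and adjusted p = 0.352 with an estimated correlation), and -0.34 without depleted CD41- replicate 3. Foxo3, a transcription factor of quiescence, was lower by -1.16 ± 0.22 (adjusted p = 0.00886), while the 14 quiescence genes as a list were not called by camera (adjusted p = 0.124) and were called by fry (adjusted p = 0.0146). With the neutrophil score as covariate, camera called quiescence in control mice (median -0.54, adjusted p = 0.0199) and not in depleted mice (0.02, adjusted p = 0.366). The same was seen for immediate early and stress genes (-0.48, adjusted p = 0.0199, and -0.46, adjusted p = 0.0678).

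By camera, lists of neutrophil, macrophage, and endothelial and stromal genes ranked higher in CD41+ cells, beside the megakaryocyte and erythroid lists. The 12 neutrophil genes all had positive fold changes, with a median of 1.41 and 0 passing over all genes (1 higher when adjusted over the list alone, camera adjusted p = 7.66e-05, and adjusted p = 0.351 with an estimated correlation). They took 4.25 ± 2.39% of counts in the CD41+ libraries (n = 5) and 1.62 ± 1.12% in the CD41- libraries (n = 6), a difference with a two-sided exact permutation p = 0.039. That test was chosen after the result was seen and permuted libraries across both treatments. When labels were split within each treatment, 29 of the 100 splits gave the list as small a camera p. The neutrophil median was 0.77 without control CD41+ replicate 2. Of 7 endothelial and stromal genes, 3 were higher and 1 was lower (6 higher and 1 lower when adjusted over the list alone), with a median of 2.06 (adjusted p = 0.000215, and adjusted p = 0.238 with an estimated correlation). Cldn5, an endothelial tight-junction gene, was higher by 1.60 ± 0.29 (adjusted p = 0.00755). Cxcl12, also on this list, stood at 136.5 ± 74.5 CPM in control CD41+ and 1.23 ± 0.684 CPM in control CD41- cells. In depleted mice it was 243 ± 93.8 CPM in CD41+ cells. Depleted CD41- replicates 1 and 2 held 1.53 and 0.209 CPM, and replicate 3 held 284.5 CPM, as much as CD41+ libraries. The stromal gene Kitl had no count in control CD41- cells and 4.75 ± 2.35 CPM in control CD41+ cells, at least 18.3-fold higher against a floor of 3 counts over the group. Ibsp, the bone sialoprotein gene, had no count there either and reached 12.0 ± 5.27 CPM in control and 26.8 ± 7.54 CPM in depleted CD41+ cells, at least 46.3-fold higher in control mice (adjusted p = 0.000247 over both treatments). Among 10 macrophage genes, 2 were higher and 0 lower, with a median of 1.12 (adjusted p = 0.000291, and adjusted p = 0.297 with an estimated correlation), or 0.71 with the neutrophil score as covariate. The myeloid priming list had 0 of 15 genes called and a median of 1.04 (adjusted p = 0.0116, and adjusted p = 0.502 with an estimated correlation), and its median was -0.00122 without control CD41+ replicate 2 and -0.00785 with the neutrophil score as covariate. It was also not called without control CD41- replicate 1 (0.87) or depleted CD41+ replicate 1 (0.78).

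Averaged over treatments, 724 genes passed, 367 higher and 357 lower in CD41+ cells. Of these, 498 showed no overlap of libraries between the fractions within either treatment. For a gene not picked by its test, chance leaves no overlap in 10% of splits of 3 against 3 and in 20% of splits of 2 against 3. The called genes were picked on the same libraries, so their lack of overlap is no separate support. Without TMM factors, scaling by library size alone, the median of all genes moved from -0.03 to -0.12 and the split became 250 higher and 445 lower. Of 76 named genes called, 38 also passed in each of the 11 fits that left out 1 library, among them Itga2b, Gp1bb, Gp5, Gata1, Treml1, Clu, Hlf, Procr, Flt3, Cd27, Rrm1, Ccne2, Ccnb1 and mt-Nd5. The count fell to 300 without control CD41+ replicate 2, to 401 without depleted CD41- replicate 2, to 417 without control CD41+ replicate 1, to 437 without depleted CD41- replicate 1 and to 481 without control CD41- replicate 3.

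**Figure D1:**
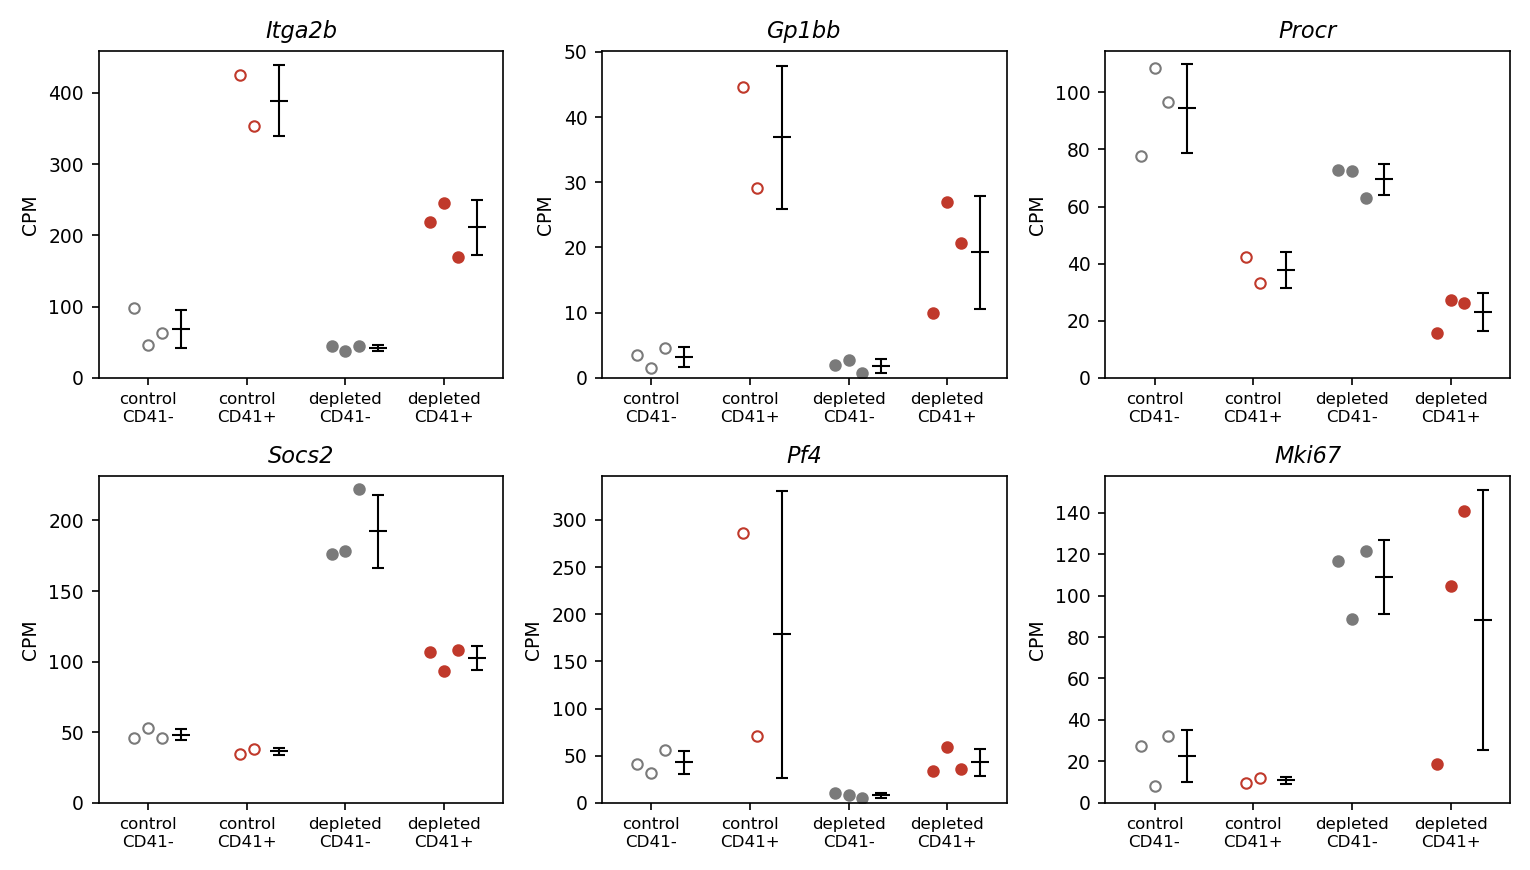
CPM of 6 genes in each library, with open points for control and filled points for depleted mice, grey for CD41- and red for CD41+ cells, and bars for mean ± SD (n = 3, 2, 3 and 3). Itga2b and Gp1bb were higher and Procr was lower in CD41+ cells, and Socs2 ran from 34.5 to 222 CPM with all depleted libraries above all control libraries.

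In control mice alone, cell-cycle and megakaryocyte transcripts were among those higher in CD41+ cells. There, 22 of 32 mitosis genes and 19 of 34 replication genes were higher and 0 were lower in either list (29 higher and 1 lower, and 27 higher and 0 lower, when adjusted over the list alone). Their medians were 1.18 and 0.79, and Rrm1 rose from 372 ± 39.8 to 942 ± 47.8 CPM (log2 1.34 ± 0.16, adjusted p = 0.00198). With 9 of 31 megakaryocyte genes higher and 0 lower (14 and 0 when adjusted over the list alone), these were the 3 lists that held with an estimated correlation (adjusted p = 0.047 with an estimated correlation for each). Lists called with the preset correlation only included platelet (median 1.60, adjusted p = 0.117 with an estimated correlation), erythroid (1.41, 0.308), neutrophil (2, 0.473), macrophage (1.56, 0.328), endothelial and stromal (1.71, 0.342) and mitochondrially encoded genes (-1.06, 0.132), the last with 4 of 7 lower. Some of these rested unevenly on the 2 control CD41+ libraries. As mean deviation in log2 CPM from the gene's mean over libraries, neutrophil genes stood at -0.36 in replicate 1 and 2.04 in replicate 2. Endothelial and stromal genes stood at 1.36 and 0.18. The means in control CD41- cells were -0.76 and -1.41. Itga2b was higher by 2.50 ± 0.26 (adjusted p = 0.00198). Pde10a, a cyclic nucleotide phosphodiesterase, had no count in control CD41- cells and 14.2 ± 0.764 CPM in control CD41+ cells, at least 54.6-fold higher. Among the named genes that passed in each fit that left out 1 library, Zfp608 had the largest decrease (log2 -4.06 ± 0.48, adjusted p = 0.00198). The nuclear RNA Malat1 stood at 2380 ± 812 CPM in control CD41- and 278 ± 124 CPM in control CD41+ libraries. In all, 352 genes passed, 212 higher and 140 lower, and none of their libraries overlapped. The split was 129 higher and 157 lower with library size alone. With 2 control CD41+ libraries the count depended on single libraries: 48 genes passed without control CD41+ replicate 2, 132 without its replicate 1, 130 without control CD41- replicate 3, 210 without control CD41- replicate 1, 223 and 234 without depleted CD41- replicates 1 and 3, and 545 without depleted CD41+ replicate 1.

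In depleted mice alone, the megakaryocyte difference was present and the mitosis difference was not detected. Gp5 was higher by 2.90 ± 0.33 in CD41+ cells (adjusted p = 0.00174), as was the tubulin gene Tuba8 with the same adjusted p (2.90 ± 0.34), and Itga2b by 2.32 ± 0.25 (adjusted p = 0.00134). Megakaryocyte genes had 2 of 31 higher and 0 lower (15 and 0 when adjusted over the list alone), with an adjusted p = 0.0098 with an estimated correlation. For the platelet list, with 3 of 18 higher and 0 lower (7 and 0 when adjusted over the list alone), it was 0.0107. Of 32 mitosis genes 0 passed, also when adjusted over the list alone, with a median of 0.12 (adjusted p = 0.205). Camera with the preset correlation also called markers of other cells higher. These were endothelial and stromal (median 2.02, adjusted p = 4.31e-05), neutrophil (0.78, 0.00281), mast cell and basophil (1.54, 0.00353) and macrophage genes (0.58, 0.0281). Replication was called too (0.13, 0.003). With an estimated correlation the adjusted p of these lists was 0.269 to 0.571. All but 1 of 34 interferon-response genes had negative fold changes, with 0 passing over all genes and 8 lower when adjusted over the list alone (median -0.67, adjusted p = 3.66e-12, and adjusted p = 0.362 with an estimated correlation). That median was -0.33 without depleted CD41- replicate 3 and -1.03 without depleted CD41+ replicate 3. In all, 26 genes passed, 9 higher and 17 lower. That count was 5 without depleted CD41- replicate 2 and without depleted CD41+ replicate 3, 8 without depleted CD41- replicate 1, 13 without depleted CD41+ replicate 2 and 14 without depleted CD41+ replicate 1. With a block of consecutive title numbers, a pairing that the labels do not state, 158 genes passed, 90 higher and 68 lower. Deviations from the group mean correlated at 0.228, 0.343 and 0.207 within the 3 depleted pairs of such numbers, against -0.149, -0.142 and -0.102 with other libraries of that group. Deviations within a group cancel, so the negative values follow from the positive ones and are no separate evidence of a pairing. The lists were not tested with this block. Within each of these depleted pairs the interferon score, the mean deviation in log2 CPM from the gene's mean over libraries, was lower in the CD41+ library. It was -0.18 and -1.04, -0.03 and -0.75, and 0.80 and 0.07 in CD41- and CD41+ libraries. In the control pairs of such numbers it was 0.13 and -0.21, and 0.64 and 0.35.

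Fold changes of the CD41 difference in control and in depleted mice, which share no library, correlated across 13448 genes at Pearson r = 0.408 and Spearman rho = 0.437, where genes are not independent replicates. Of the genes called in control mice, 8 higher and 11 lower were also called in depleted mice, against 0.142 and 0.177 by chance. The sign was shared by 84.4% of those called higher and 95.7% of those called lower.

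How stem cells differed 24 h after platelet loss was addressed by the difference between depleted and control mice averaged over both CD41 fractions. Mitosis transcripts rose together. Of 32 mitosis genes, 31 were higher, 0 lower and 1 did not pass (all 32 higher when adjusted over the list alone), with a median log2 fold change of 1.09. Ccnb2 (chromosome 9, 70407692 to 70421547, minus strand), the mitotic cyclin B2, rose 2.20-fold (log2 1.14 ± 0.13, adjusted p = 0.000606), from 108 ± 19.2 to 370 ± 23.8 CPM in CD41- cells and from 261 ± 47.8 to 368 ± 25.9 CPM in CD41+ cells. Prc1, which bundles microtubules in the dividing cell, rose by 1.12 ± 0.13 (adjusted p = 0.000606), the kinetochore motor Cenpe by 2.25 ± 0.36 (adjusted p = 0.00302) and the spindle protein gene Nusap1 by 1.33 ± 0.16 (adjusted p = 0.000753). Mki67, the gene of the proliferation antigen Ki-67 (chromosome 7, 135689784 to 135716361, minus strand), rose by 2.67 ± 0.49 (adjusted p = 0.0131, and 0.0884 without control CD41+ replicate 1). The list was called by camera (adjusted p = 8.08e-60) and was the only one of 13 called lists to hold with an estimated correlation (adjusted p = 0.0095 with an estimated correlation). Of 34 replication genes, 13 were higher and 0 lower (29 and 0 when adjusted over the list alone), with Rrm1 at 0.75 ± 0.11 (adjusted p = 0.00177) and Exo1 at 0.91 ± 0.17 (adjusted p = 0.00681). The list had an adjusted p of 5.91e-16 (adjusted p = 0.143 with an estimated correlation).

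Some megakaryocyte and platelet transcripts fell in depleted mice. Of 31 megakaryocyte genes, 9 were lower and 0 higher (10 lower and 1 higher when adjusted over the list alone), with a median of -0.62 (adjusted p = 1.04e-07, and adjusted p = 0.0782 with an estimated correlation). Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383, plus strand), the chemokine platelet factor 4, fell 4.67-fold (log2 -2.23 ± 0.33, adjusted p = 0.00289), from 42.8 ± 12.6 to 7.79 ± 2.41 CPM in CD41- cells and from 179 ± 152 to 42.8 ± 14 CPM in CD41+ cells. Gp5 was lower by -1.81 ± 0.23 (adjusted p = 0.000887) and Plek, the platelet kinase substrate pleckstrin, by -1.53 ± 0.25 (adjusted p = 0.00459). Platelet-abundant transcripts counted 5 lower and 1 higher of 18 (6 and 2 when adjusted over the list alone, adjusted p = 0.00105, and adjusted p = 0.197 with an estimated correlation), and the 1 that rose was Clu. Itga2b itself was lower by -0.79 ± 0.18 (adjusted p = 0.0187, and 0.091 without control CD41+ replicate 1). Kit at -0.69 (adjusted p = 0.385) and Cd48 at 0.65 (adjusted p = 0.316) did not pass.

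Socs2, an inducible inhibitor of cytokine receptor signalling (ENSMUSG00000020027, chromosome 10, 95385362 to 95417180, minus strand), had the smallest adjusted p of all genes (2.92e-05). It rose 3.35-fold (log2 1.74 ± 0.13), from 48.4 ± 4.15 to 192 ± 26.0 CPM in CD41- cells and from 36.3 ± 2.63 to 103 ± 8.30 CPM in CD41+ cells. Id1 rose by 1.65 ± 0.32 (adjusted p = 0.0094, and 0.0581 without control CD41+ replicate 1). The 15 cytokine and STAT target genes counted 3 higher and 1 lower (4 and 2 when adjusted over the list alone) and were not called as a list by camera (adjusted p = 0.0633, and adjusted p = 0.197 with an estimated correlation), while fry called them (adjusted p = 0.013). In the opposite direction, the immediate early transcription factor gene Jun fell by 1.25 ± 0.17 on the log2 scale (adjusted p = 0.00153), and 3 of 15 immediate early and stress genes were lower and 0 higher (4 and 0 when adjusted over the list alone, adjusted p = 0.00205, and adjusted p = 0.205 with an estimated correlation). Their median of -0.37 was -0.16 without control CD41+ replicate 2 and -0.61 without depleted CD41+ replicate 3.

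Some long-term stem cell, interferon and sterol genes were lower after depletion. Of 22 long-term stem cell genes, 6 were lower and 0 higher (7 lower and 1 higher when adjusted over the list alone), with Txnip, a thioredoxin inhibitor, at -1.25 ± 0.15 (adjusted p = 0.000757) and Sult1a1 at -1.07 ± 0.15 (adjusted p = 0.00174). The list had a median of -0.41 (adjusted p = 0.000107, and adjusted p = 0.197 with an estimated correlation). Interferon genes counted 3 lower and 1 higher of 34 (5 and 1 when adjusted over the list alone), with Ifi44 at -1.26 ± 0.19 (adjusted p = 0.00214), and the list's adjusted p was 0.000401 (adjusted p = 0.586 with an estimated correlation). Its median of -0.32 was -0.18 without control CD41+ replicate 2, -0.20 without depleted CD41- replicate 1, -0.51 without depleted CD41- replicate 3 and -0.59 without depleted CD41+ replicate 3. Among 19 genes of cholesterol synthesis, 5 were lower and 0 higher (9 and 0 when adjusted over the list alone), with Insig1, a sterol-regulated brake on that pathway, at -1.17 ± 0.21 (adjusted p = 0.00582). Their median was -0.48 (adjusted p = 1.02e-06, and adjusted p = 0.197 with an estimated correlation). Nfkbia, which encodes an inhibitor of NF-kB, fell by 0.80 ± 0.12 on the log2 scale (adjusted p = 0.0021), the 1 gene lower among 18 NF-kB genes. That list's adjusted p was 0.0174, lost with an estimated correlation (adjusted p = 0.201 with an estimated correlation) and without control CD41+ replicate 2 or control CD41- replicate 3 (medians of -0.16 and -0.23).

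Some genes of protein turnover, ribosome assembly and respiration were higher after depletion, while some ribosomal protein genes were lower. All 30 proteasome genes had positive fold changes, with 12 higher and 0 lower (24 and 0 when adjusted over the list alone), led by Psmc1 at 0.73 ± 0.12 (adjusted p = 0.00432) and Psmd6 at 0.71 ± 0.13 (adjusted p = 0.00599). Of 29 ribosome assembly genes, 7 were higher and 0 lower (13 and 0 when adjusted over the list alone), with the nucleolin gene Ncl at 0.94 ± 0.15 (adjusted p = 0.00347). Oxidative phosphorylation counted 8 higher and 0 lower of 55 (28 and 0 when adjusted over the list alone). Of 44 ribosomal protein genes, 7 were lower and 0 higher (14 and 0 when adjusted over the list alone), with Rpl13 at -0.56 ± 0.10 (adjusted p = 0.00435). The adjusted p of these 4 lists was 4.91e-12, 5.17e-07, 1.03e-10 and 7.06e-09, and the adjusted p with an estimated correlation was 0.151, 0.197, 0.197 and 0.429. The ribosomal protein median of -0.34 was -0.22 without control CD41+ replicate 1.

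Myh10, a non-muscle myosin heavy chain (chromosome 11, 68691559 to 68816632, plus strand), rose 8.21-fold (adjusted p = 0.00064), from 4.31 to 19.7 CPM in CD41- and from 1.46 to 21.5 CPM in CD41+ cells. Podxl, a sialomucin related to CD34 (chromosome 6, 31519488 to 31563981, minus strand), rose 5.92-fold (adjusted p = 0.000606), Plek2 by 3.65 ± 0.55 (adjusted p = 0.00191) and Cox4i2 by 2.37 ± 0.32 (adjusted p = 0.00126). Ctsf, a lysosomal protease, fell by 1.58 ± 0.19 on the log2 scale (adjusted p = 0.000749), and the glycolytic aldolase gene Aldoc fell by 1.74 ± 0.27 (adjusted p = 0.00272).

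Averaged over fractions, camera did not call the marker lists of other cell types after depletion. The neutrophil list had a median of 0.22 (adjusted p = 0.858), the macrophage list 0.39 (adjusted p = 0.172) and the endothelial and stromal list 1.70 (adjusted p = 0.172), or 1.21 with Kitl set to its floor, and 0 genes of these 3 lists passed. The stromal median was 0.595 without depleted CD41- replicate 3, and 3.11 without control CD41+ replicate 1, where the list passed (adjusted p = 0.0286). The macrophage list passed without control CD41- replicate 1 (median 0.68, adjusted p = 0.0161), and the neutrophil median was -0.02 without control CD41+ replicate 1 and -0.155 without depleted CD41- replicate 1. Within single fractions, camera called macrophage markers higher in CD41- cells (median 0.85, adjusted p = 0.0178, and 0.499 with an estimated correlation). It called T and NK cell markers lower in CD41+ cells (-1.36, adjusted p = 0.00239, and 0.162 with an estimated correlation).

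**Figure D2:**
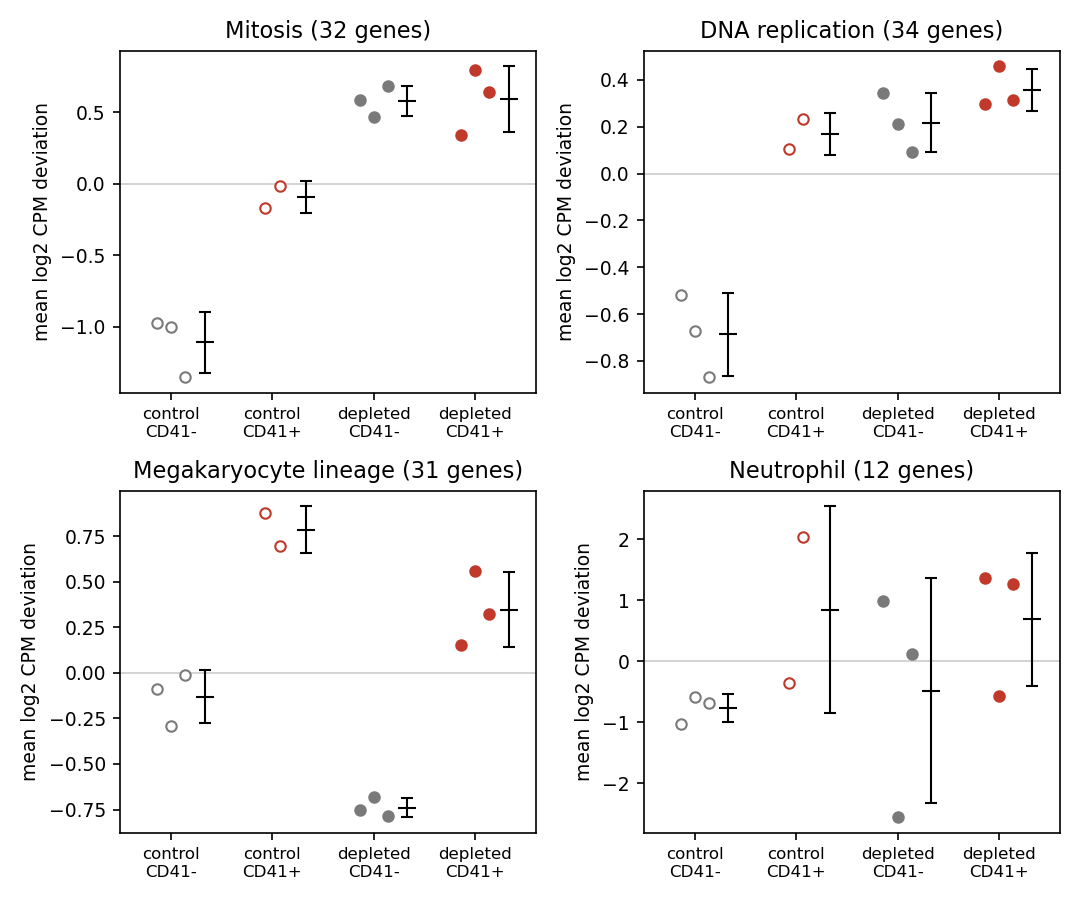
Mean deviation in log2 CPM of the genes of 4 lists in each library, from the gene's mean over libraries, with open points for control and filled points for depleted mice, grey for CD41- and red for CD41+ cells, and bars for mean ± SD (n = 3, 2, 3 and 3). Mitosis scores averaged -1.11 in control CD41- cells and -0.09, 0.58 and 0.59 in control CD41+, depleted CD41- and depleted CD41+ cells, and neutrophil scores spread most in depleted CD41- cells (SD 1.84).

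Averaged over fractions, 851 genes passed, 484 higher and 367 lower in depleted mice, of which 623 showed no overlap of libraries within either fraction. The counts were 481 and 321 with library size alone. Of 73 named genes called, 32 passed in each of the 11 fits that left out 1 library, among them Ccnb2, Prc1, Cenpe, Nusap1, Pf4, Gp5, Plek, Socs2, Jun, Txnip, Ifi44, Myh10 and Podxl. The count fell to 291 without control CD41+ replicate 1, to 370 and 404 without depleted CD41- replicates 3 and 1, to 454 without depleted CD41+ replicate 3 and to 459 without control CD41+ replicate 2.

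**Figure D3:**
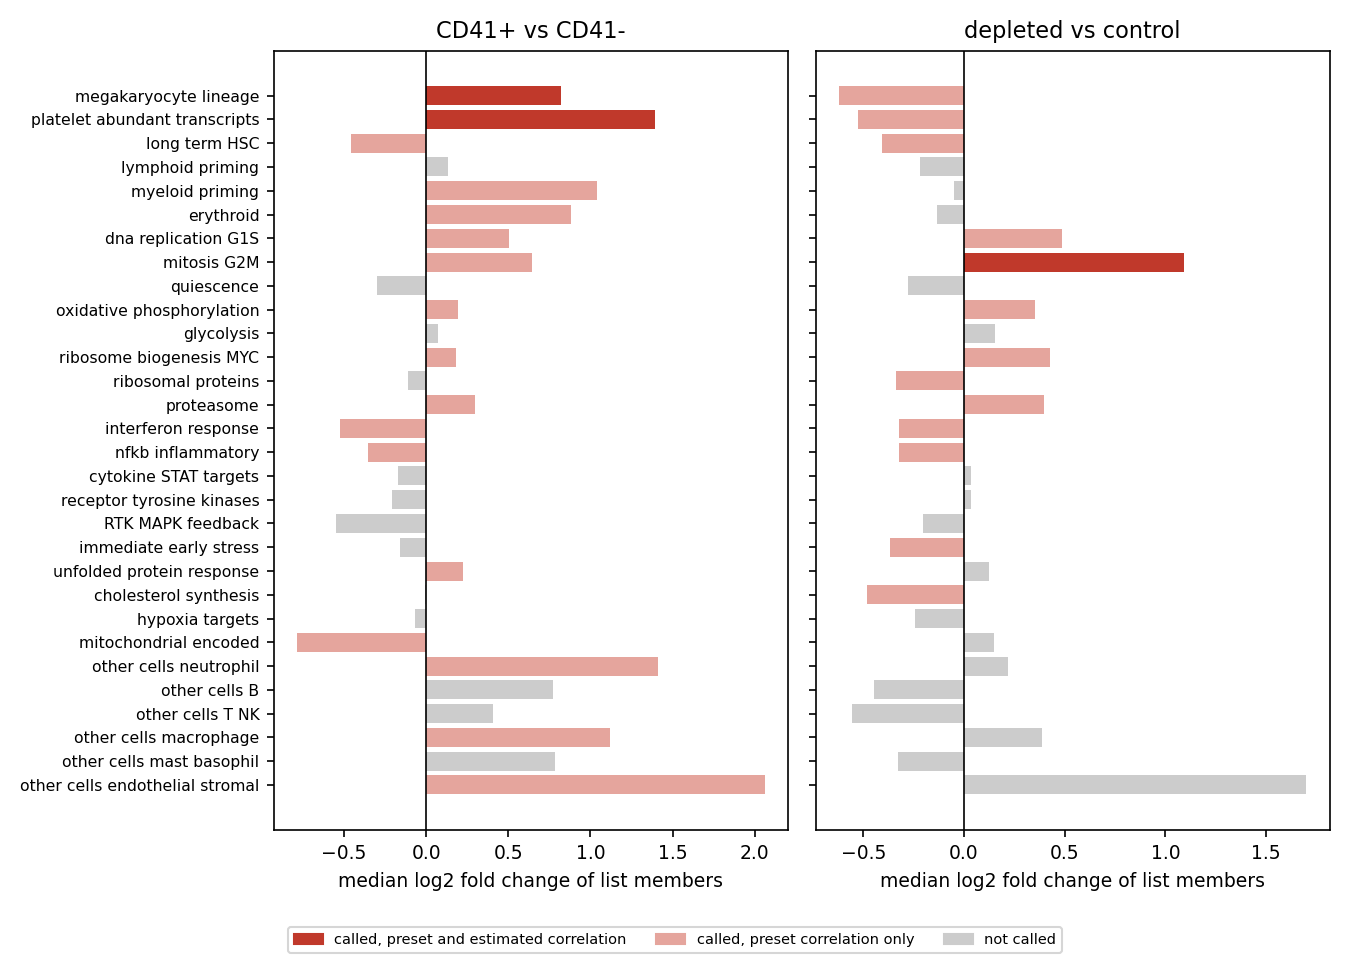
Median log2 fold change of the measured genes of 30 lists, for CD41+ against CD41- cells (left) and depleted against control mice (right), with colour for lists called by camera with preset and estimated correlation, with the preset correlation only, or not called. Mitosis (1.09) after depletion, and megakaryocyte (0.82) and platelet (1.39) transcripts in CD41+ cells, held under both settings.

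In CD41- cells alone, mitosis and replication genes were higher and some megakaryocyte genes lower in depleted than in control mice. Mitosis had 30 of 32 genes higher and 0 lower (32 and 0 when adjusted over the list alone), with a median of 1.59 (adjusted p = 0.00288 with an estimated correlation). Replication had 20 of 34 higher and 0 lower (30 and 0 when adjusted over the list alone), with a median of 0.83 (adjusted p = 0.0456 with an estimated correlation). Hmmr, a spindle protein gene, rose from 21.7 to 124 CPM (log2 2.51 ± 0.31, adjusted p = 0.000801), and Fancd2, of the Fanconi anaemia repair pathway, by 2.51 ± 0.40 (adjusted p = 0.00346). Gp5 was lower by -2.36 ± 0.33 (adjusted p = 0.00147), 1 of 4 megakaryocyte genes lower and 0 higher of 31 (12 lower and 1 higher when adjusted over the list alone, adjusted p = 1.77e-06, and adjusted p = 0.109 with an estimated correlation). The interferon list was not called, and its median of -0.21 was -0.51 without depleted CD41- replicate 3 (adjusted p = 5.14e-05), -0.06 without its replicate 2, 0.04 without its replicate 1 and 0.07 without control CD41- replicate 2. In this fraction 429 genes passed, 309 higher and 120 lower. Their number was 169, 175 and 256 without depleted CD41- replicates 3, 1 and 2, and 215 without control CD41- replicate 3. This comparison and that of CD41 in control mice share the control CD41- libraries, which stood apart in Malat1 (1450 to 2980 CPM, against 83.9 to 477 CPM in the other 8).

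In CD41+ cells alone, 14 genes passed, 5 higher and 9 lower. Myh10 rose by 3.89 ± 0.57, Podxl by 2.99 ± 0.44 and Socs2 by 1.49 ± 0.20 (adjusted p = 0.0228 for each), and Txnip was lower by -1.32 ± 0.23 (adjusted p = 0.0454). All 32 mitosis genes had positive fold changes, with 0 passing over all genes and 15 higher when adjusted over the list alone (median 0.56, adjusted p = 1.2e-14, and adjusted p = 0.162 with an estimated correlation). For 31 megakaryocyte genes 0 passed and 7 were lower when adjusted over the list alone (median -0.37, or -0.23 without control CD41+ replicate 1, adjusted p = 7.45e-05, and adjusted p = 0.162 with an estimated correlation). At p under 0.05 without adjustment, 1646 genes stood out. The call of each named gene rested on single libraries: the count was 0 without control CD41+ replicate 1, without depleted CD41+ replicate 2 and without depleted CD41+ replicate 3. It was 2 to 8 without control CD41- replicate 1, control CD41+ replicate 2 or depleted CD41- replicates 1 and 3, and 57 without depleted CD41+ replicate 1. Myh10, Podxl and Socs2 had an adjusted p of 0.241 without control CD41+ replicate 1, and Txnip 0.266 without depleted CD41+ replicate 3.

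The depletion responses of the fractions, which share no library, correlated across genes at Pearson r = 0.249 and Spearman rho = 0.32. Of the 309 genes called higher in CD41- cells, 4 were also called in CD41+ cells against 0.115 by chance, and of the 120 called lower, 8 were, against 0.0803 by chance. The sign was shared by 90.3% and 95.8% of them.

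Whether CD41+ and CD41- stem cells respond differently to platelet loss was tested as the difference between the 2 responses. At the level of lists, the mitosis response was smaller in CD41+ cells by a median log2 of -1.06, with 0 of 32 genes passing over all genes and 26 lower when adjusted over the list alone. This list was called by camera (adjusted p = 4.57e-33) and held with an estimated correlation (adjusted p = 0.0488 with an estimated correlation). For replication the median was -0.66, with 16 of 34 lower when adjusted over the list alone (adjusted p = 6.98e-19, and adjusted p = 0.145 with an estimated correlation). The megakaryocyte list had a median of 0.14 and was not called (adjusted p = 0.297), with medians of -0.01 without control CD41- replicate 1 and -0.07 without control CD41+ replicate 2. The genes with the smallest p were Zfp608 (3.32), Cdca8 (-1.19), Ccnb2 (-1.28), Rrm1 (-1.12) and Ubqln2 (4.46), each with an adjusted p of 0.304. By edgeR 0 of 13448 genes passed, with 825 at p under 0.05 without adjustment, while DESeq2 called 35 and limma voom 0. Without the low-count filter edgeR called 178 genes, of which 3 lay outside the 13448. In simulated data this test recovered 1.99% of genes at a fold of 2 and 34.8% at a fold of 4. The 0 calls thus do not show that single genes responded alike.

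Receptor tyrosine kinases, named in the title of the series, were examined as a list of 25 measured genes. After depletion 0 of them passed, averaged over fractions (median 0.04, mean 0.22, adjusted p = 0.858) or in CD41- cells (adjusted p = 0.574) or in CD41+ cells (adjusted p = 0.792), and 0 passed when adjusted over the list alone. The smallest p values of the average belonged to Insr (log2 1.06, adjusted p = 0.109) and Erbb3 (adjusted p = 0.106). Of 8 feedback genes of this signalling pathway, Dusp6, a phosphatase that acts on ERK, was lower by -0.58 ± 0.14 (adjusted p = 0.0256, and 0.107 without control CD41+ replicate 1), and the list was not called (adjusted p = 0.667). Between CD41 fractions 1 kinase gene was lower, Flt3, and 1 was higher, Egfr (3 higher and 4 lower when adjusted over the list alone), and the list was not called (adjusted p = 0.177). Egfr had no count in control CD41- cells and 1.73 ± 2.08 CPM in control CD41+ cells (adjusted p = 0.0287 over both treatments). That mean was at least 6.68-fold higher, but the SD of its 2 libraries exceeded it, so the bound does not hold for each library. The call of Egfr also depended on control CD41+ replicate 1.

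The remaining lists gave few calls. Between CD41 fractions, oxidative phosphorylation had 3 of 55 genes higher (median 0.20, adjusted p = 1.65e-05, and adjusted p = 0.351 with an estimated correlation) and ribosome assembly 0 of 29 (median 0.18, adjusted p = 0.00384, and adjusted p = 0.351 with an estimated correlation), with medians of 0.11 and 0.09 when scaled by library size alone. Unfolded protein response genes counted 4 higher, among them the chaperone gene Hspa5 (0.69 ± 0.14, adjusted p = 0.0131), and 1 lower of 20 (adjusted p = 0.0116, and adjusted p = 0.32 with an estimated correlation), a call lost without control CD41+ replicate 2 (median 0.145) and with the neutrophil score as covariate (0.11). NF-kB genes had 2 of 18 lower (adjusted p = 0.0199, and adjusted p = 0.279 with an estimated correlation), lost without control CD41+ replicate 1 (median -0.36). Not called by camera between fractions were glycolysis (2 of 17 higher, Ldha at 0.78 ± 0.12, adjusted p = 0.232 for the list), ribosomal proteins (0.191), cytokine and STAT targets (0.431), receptor feedback genes (0.105), immediate early genes (0.177), cholesterol synthesis (0.714), and hypoxia targets (0.952). The same held for markers of B cells (0.163), T and NK cells (0.163) and mast cells and basophils (0.051). After depletion, averaged over fractions, the lists not called by camera were lymphoid (0.232), myeloid (0.759) and erythroid (0.667) genes, quiescence (0.0885), glycolysis (0.737), unfolded protein response (0.314), hypoxia targets (0.0871), and mitochondrially encoded genes (0.737). Nor were markers of B cells (0.195), T and NK cells (0.108) and mast cells and basophils (0.858). Fry, a rotation test that does not compare a list with other genes and asks whether its genes move on balance in 1 direction (or, in its mixed form, in either), called 12 lists between fractions and 15 after depletion. Among these, camera had not called quiescence and receptor feedback genes (adjusted p = 0.0234 by fry) between fractions, nor quiescence (0.013), cytokine and STAT targets, hypoxia targets (0.0155) and T and NK cell markers (0.0161) after depletion.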

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

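The results in this paragraph stood out because the depletion response of a list or gene differed between CD41+ and CD41- cells. Of the 3 patterns weighed after it, the fall of some megakaryocyte transcripts and the variation of neutrophil transcripts did not meet that rule and were picked from the results, and the tests with platelet genes, with the neutrophil score and with neutrophil counts were chosen after the result was seen. By camera on the difference of responses, 7 lists passed: mitosis (median log2 -1.06), DNA replication (-0.664), T and NK cell markers (-1.61), interferon response (-0.408), mitochondrially encoded genes (0.416), ribosomal proteins (0.154) and macrophage markers (-0.897). With an estimated correlation only mitosis passed. Among 346 named genes, 5 moved in opposite directions without overlap of libraries in both fractions, Slamf1 (-1.13), Pde10a (-6.13), Map7d3 (3.4), Zfhx3 (2.34) and Dtl (-1.33). The value of Pde10a was fitted against control CD41- libraries without a count of it, so its size is not determined. None of them passed the test of the difference (adjusted p between 0.407 and 0.606), and chance alone leaves no overlap in 10% of splits of 3 against 3 and 20% of splits of 2 against 3.

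Cell-cycle transcripts were lower in control CD41- cells than in the other groups. The mitosis median between CD41 fractions of control mice, 1.18, was 1.12 with the neutrophil score as covariate, 1.07 with libraries thinned to the smallest total and 1.21 after removal of a trend with transcript length. Carried-over neutrophil RNA is thus argued against. Thinning keeps expected CPM ratios, so it could not decide on depth. Control totals were close, with 3.46 to 3.88 M counts in CD41- and 3.78 to 4.27 M in CD41+ libraries. Mitosis genes had a median length of 1396 bp against 1369 bp for all genes, so a length trend had little to act on. The 3 control CD41- libraries had 1450 to 2980 CPM of Malat1, against 83.9 to 477 CPM in the other 8. A difference in RNA or library quality, or between mice or sort days, was not tested and stays open.

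Some megakaryocyte transcripts were lower after platelet depletion, and platelets stuck to control cells would give such a fall. In CD41- cells Ppbp, Pf4 and Tubb1 together lost 41.1 CPM, and Ppbp stood at 0.495 with an SE of 0.883 in CD41+ cells, so platelets as a source stay open. The list median of -0.621 was -0.625 with the neutrophil score and -0.61 with thinned libraries. Thinning keeps expected fold changes, so it could not decide on depth. Averaged over fractions, the neutrophil list itself differed little after depletion (median 0.22, camera adjusted p = 0.858). That average joined a median of 0.73 in CD41- cells and -0.44 in CD41+ cells, neither called (camera adjusted p = 0.378 and 0.485). In the average, dilution by neutrophil RNA thus had little to act on. In CD41- cells alone, where the megakaryocyte median was -0.70, dilution stays open.

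Neutrophil transcripts took from 0.429% to 7.54% of counts. The ratio of later to earlier neutrophil genes ranged 5.89-fold (2.67-fold without the most extreme library), so 1 source of fixed composition stays open. The share was higher in CD41+ libraries (exact permutation p = 0.039), and whether the transcripts came from other cells or from the sorted cells was not resolved.

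Labels were also split in other ways. For the number of genes, 1 of the 100 splits reached the real count of 724 between CD41 fractions (the real split itself, highest other 9) and 1 of the 100 splits that of 851 after depletion (highest other 228), so chance splitting is excluded at this resolution. For the number of called lists, 9 of the 100 splits reached 17 between fractions (highest other 18) and 20 of the 100 splits reached 13 after depletion (highest other 19), so chance cannot be excluded for those counts. By camera p, 1 of the 100 splits was as small for mitosis after depletion (2.69e-61, next 4.29e-52) and 1 of the 100 splits for megakaryocyte genes after depletion (2.09e-08, next 2.35e-08). Between fractions it was 2 of the 100 splits for megakaryocyte genes (1.37e-18, smallest other 2.41e-19) and 12 of the 100 splits for mitosis (1.34e-18, smallest other 1.52e-34), so chance cannot be excluded for the last. Of the other lists called between fractions, 29 of the 100 splits did as well for neutrophil, 28 for interferon, 19 for macrophage, 19 for oxidative phosphorylation, 20 for ribosome assembly, 15 for erythroid, 11 for unfolded protein response, 55 for myeloid, 7 for replication and 6 for NF-kB genes. After depletion the numbers were 39 for interferon, 18 for ribosomal proteins, 13 for immediate early, 9 for NF-kB, 7 each for replication, oxidative phosphorylation and ribosome assembly, and 6 for long-term stem cell genes. These splits alone do not exclude chance for these lists, and they did not keep consecutive title numbers together, a pairing that the labels do not state. From 1 to 4 of the 100 splits did as well for the remaining called lists. For CD41 in depleted mice (26 genes) and depletion in CD41- cells (429 genes), 1 of 10 splits reached the real count, and 10 splits are too few to tell.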

How the results depend on the processing

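Counts of changed genes depended on the tool, the filter and single libraries, and the cause was not tested. The comparisons are A (CD41 in control mice), B (CD41 in depleted mice), C (depletion in CD41- cells), D (depletion in CD41+ cells), E (difference of responses), F (CD41 on average) and G (depletion on average), and 7 values run from A to G. Without a filter (25098 genes) 1142, 387, 862, 317, 178, 1674 and 1336 genes passed, of which 23, 26, 17, 8, 3, 95 and 44 lay outside the main filter. DESeq2 called 994, 204, 851, 266, 35, 1441 and 1407. Limma voom called 176, 104 and 8 in A, B and D, the fit without robust 7 in D, fits on the compared groups alone 143 and 0 in A and D, and a block of consecutive title numbers, a hint and not a known pairing, 158 in B and 2 in E. The neutrophil score, a covariate added after the results were seen, gave 154, 16 and 238 in A, B and F. Leaving out 1 library gave 48 to 545, 5 to 32, 169 to 560, 0 to 57, 0 to 0, 300 to 788 and 291 to 1060, where a control CD41+ library left alone was assumed to vary like the other groups. An estimated correlation left 3, 2, 2, 0, 1, 2 and 1 lists, and fry called 9, 3, 5 and 2 in A, B, D and E. In the difference of responses, 12 lists passed without control CD41+ replicate 1 and 2 without its replicate 2. The myeloid list turned sign in A with the neutrophil score (-0.0853) and across left-out libraries (-0.276 to 1.94), and in F with the score (-0.00785) and across libraries (-0.00122 to 1.33). The lymphoid list turned in B (-0.469 to 0.0516, with 0.0413 without depleted CD41- replicate 1), and ribosomal proteins in E (-0.0099 to 0.349). The correlation of depletion responses was 0.0934 and that of CD41 differences 0.154 without a filter, and the latter was 0.248 without control CD41+ replicate 1. Of 5155 alternative values for 272 called results, 4165 stayed called, 990 did not and 0 were called in the opposite direction.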

Other observations

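Of 15 genes of antigen presentation looked at after the results were seen, with no list fixed for them and no test of the group, 8 were lower after depletion, among them H2-T23 (log2 -0.96 ± 0.11, adjusted p = 0.000662) and H2-Q6 (-0.90 ± 0.10, adjusted p = 0.000606). Several of these genes are close paralogs, and how counting divided reads among them is not given in the sources used here. B2m, the light chain of class I molecules, did not pass (adjusted p = 0.531), and neither did Cd74 (adjusted p = 0.98).

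The nuclear RNA Malat1 ran from 1450 to 2980 CPM in the 3 control CD41- libraries and from 83.9 to 477 CPM in the other 8, and Kcnq1ot1 was 107 ± 12.4 CPM in control CD41- cells and lower in CD41+ cells on average (log2 -2.38, adjusted p = 0.00521). Genes called lower in control CD41+ cells had a median transcript length of 1852 bp, against 1194 bp for those called higher and 1369 bp for all tested genes. In depleted mice the order was the opposite, with 1160 bp for the 17 genes called lower and 2068 bp for the 9 called higher. Over all tested genes the trend did not reverse. The Spearman correlation of length and log2 fold change was -0.115 in control and -0.118 in depleted mice. Sparc, an extracellular matrix gene that is also on the megakaryocyte and platelet lists, was higher in CD41+ cells (log2 2.59, adjusted p = 0.00392). It stood at 49 against 8.94 CPM in control and 120 against 18.6 CPM in depleted mice.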
